A study of Homo sapiens with 20 samples.

How the data were processed

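RNA was measured in 20 samples of peripheral blood mononuclear cells that had been enriched for CD8+ T cells by magnetic negative selection, with 1 array per patient. Per the labels' protocols, RNA was extracted with Trizol, treated against genomic DNA, and amplified and biotin-labelled with a whole-transcript kit made for very small RNA inputs. The labels place 10 patients among those hypersensitive to sulfonamide antibiotics and 10 among those who tolerated them. They give no covariate for a patient that could enter a fit, no array batch or date, and no cytotoxicity result for any sample.

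The deposited table holds 1 normalized log2 expression value per feature and array, made by the authors with RMA in Affymetrix Expression Console 1.14.46, per the submitters' processing notes. RMA corrects background, quantile-normalizes the probes across arrays and summarises each feature by median polish, so values are relative within this set of arrays. The log2 scale was read from the values, which ran from 1.15 to 14.2 with array medians between 4.79 and 4.98 over transcript clusters. Any filter on features or arrays, and any batch correction, is not given in the sources used here. Scanner intensities were not used here, so signal above background could not be judged per feature, and an array has no read depth: the number of arrays limits the precision. Quantile normalization gives every array nearly the same overall distribution, so a shift shared by most genes would not be visible.

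Of the 70523 features, 67528 were transcript clusters and 2995 were control, spike-in or probe set features. The platform annotation gave 23781 features a single gene symbol, 1543 several and 45199 none. Of those with a single symbol, 21497 had a gene ID that led to the same symbol in the current gene table, 1974 matched it by symbol and 310 were not in it and kept the annotation's symbol. Features of Y-linked genes and of the X-inactivation transcripts were left out of every step. The remaining 23670 features gave 22378 genes, of which 455 had several features, and the feature with the highest mean over all arrays stood for its gene. Genes whose mean over all 20 arrays lay below the median of those means, a log2 value of 5.73, were not tested, which left 11189. Gene coordinates are not given, because the build behind the annotation is not given in the sources used here. Probes of near-identical copies, as in the HSPA1A, histone and ubiquitin-specific peptidase families, can read more than 1 gene, and those genes are reported as uncertain.

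Each gene was tested with limma 3.58.1 (lmFit and eBayes, 2-sided) in R 4.3.3, with group as the single factor and Benjamini-Hochberg adjusted p at or below 0.05 as the threshold. All adjusted p-values given for single genes are from limma. A set of 27 gene lists covering cell identity, immune and stress responses, drug metabolism and other blood cell types was compared with camera at a preset inter-gene correlation of 0.01, adjusted over the 26 lists with at least 5 tested genes. Camera with an estimated correlation (with statmod 1.5.0 installed) and fry were run beside it, in the fit as designed only. Camera compares a list's genes with all other genes; fry asks whether a list's genes moved one way on balance. The level of a list in an array was the mean of its tested genes, each centred on its mean over the 20 arrays, and group means of that level were compared by a 2-sided permutation test with 100000 resamples, adjusted over 27 lists. Intervals of 95% for list levels came from the pooled spread between arrays. The spread of the groups was compared as the median over genes of the log2 ratio of variances, against 100 seeded splits of the arrays into 10 and 10.

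The groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule took up to 12 genes per direction past the threshold. A direction with fewer was filled to 12 with the smallest unadjusted p among genes with an absolute log2 difference of at least 0.3. From each list it took the members past the threshold adjusted over the list alone, or otherwise the 2 with the smallest p, and it always took 13 genes of CD8 T cells and sulfonamide metabolism. Genes whose level can follow a common germline deletion, unnamed loci and the small RNA families that the rule lists were not named. SCARNA17, a small RNA outside those families, was kept. Single genes are given only as group means, SDs and differences.

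Alternatives covered the filter on dim genes, normalization between arrays, features per gene, the prior of limma, array weights, a rank test, all transcript cluster features, marker levels of other cells as covariates, the style of the sample titles as a block, and each array left out in turn. The titles follow 2 styles, numbered (14 arrays) and lettered (6 arrays); what the styles mark is not given in the sources used here. After the data were seen, fits without the 3 arrays farthest from the median array and with 2 principal components as covariates were added. The steps were tested on simulated values drawn from the real gene means and spreads, with independent genes. Among 11189 genes, limma recovered 98 of 100 genes shifted by a log2 value of 1 and 84 of 100 shifted by 0.5, with 6 wrong calls. Camera called the simulated interferon and heat shock lists and 0 other lists, and a true log2 variance ratio of 1 was fitted as 0.98. The real lists had a median estimated correlation of 0.414 among their genes. The recovery of genes and the 0 other lists therefore show that the steps run correctly, and do not carry over to the real arrays. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.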

Results

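Gene expression was measured on whole-transcript arrays in CD8+ T cell-enriched blood mononuclear cells from 20 patients treated with sulfonamide antibiotics. Of these, 10 were recorded as hypersensitive and 10 as tolerant, with 1 array for each patient, so the spread within a group is a spread between patients. The arrays were evenly scaled, with median log2 values of 4.79 to 4.98 in the hypersensitive and 4.79 to 4.91 in the tolerant group. No 2 arrays were identical, and the highest correlation of gene-centred values between any 2 was 0.494. Markers of the enriched cells lay above the mean log2 value of 5.73 that a gene needed to be tested: CD8A had a mean log2 value of 7.60 ± 0.25 in hypersensitive and 7.69 ± 0.27 in tolerant patients (SD, n = 10 each), and PRF1, which encodes perforin, had 9.73 ± 0.49 and 9.69 ± 0.46. Some markers of cells that the selection should remove also lay above that value. CD79A of B cells had 7.61 ± 0.46 and 8.06 ± 0.59, and LYZ of monocytes 8.70 ± 0.96 and 9.31 ± 0.69. The limit is the median of all gene means, so passing it does not measure enrichment.

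The first comparison asked which genes differ in these cells between hypersensitive and tolerant patients. Genes induced by type I interferon were higher as a group in hypersensitive patients, by a mean log2 difference of 0.28, and genes of the heat shock response were lower as a group, with a mean log2 difference of -0.19 (n = 10 each). These calls of camera with a preset correlation were lost when the correlation was estimated (adjusted p = 0.155 for interferon genes and 0.152 for heat shock genes with an estimated correlation), and permutation of the list means gave adjusted p = 0.254 and 0.248. Among the 24 genes named by the rule for genes short of the threshold, HERC5, OAS3, OAS1, IFI44, EPSTI1 and USP18 were interferon genes with higher values, and DNAJB1 and HSPA1A were heat shock genes with lower ones. USP18 and HSPA1A are uncertain, since near-identical copies can share their probes. No single gene passed the threshold, and no tested gene differed between the group means by 2-fold. CD8A, CD8B, perforin and the granzymes measured here did not pass either.

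**Figure D1:**
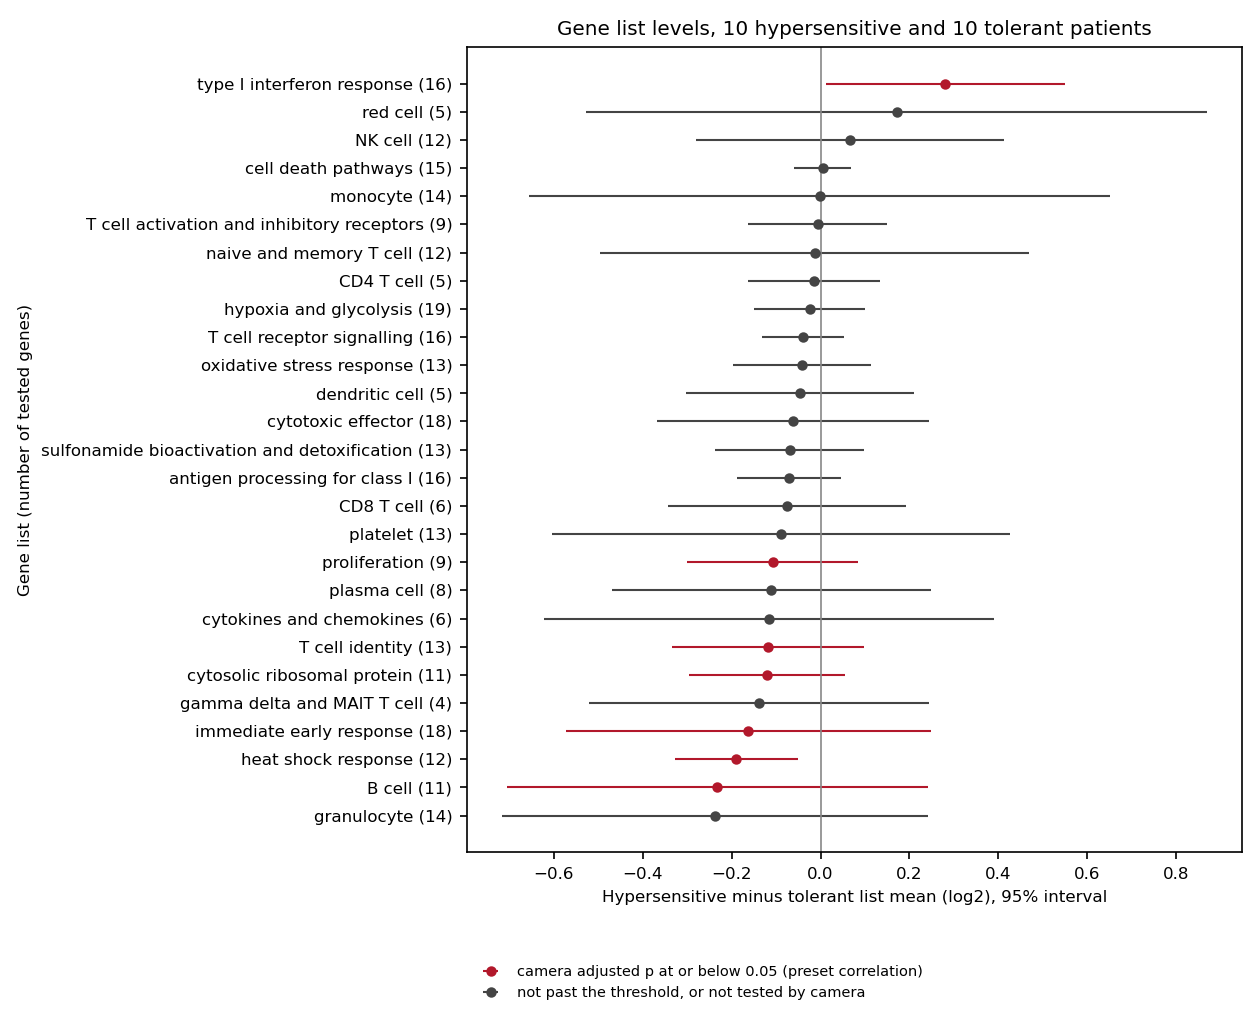
Difference in the mean level of each of 27 gene lists, hypersensitive minus tolerant, on the log2 scale (x axis), with the list and its number of tested genes on the y axis. Points are differences of group means over 10 arrays each, bars are 95% intervals from the spread between arrays, and red marks the 7 lists called by camera with a preset correlation; the intervals of the interferon list (0.012 to 0.55) and the heat shock list (-0.33 to -0.051) lie to 1 side of 0.

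The type I interferon list holds antiviral effectors that cells switch on when interferon binds its receptor. Of its 16 tested members, 15 were higher in hypersensitive patients and 8 had an unadjusted p under 0.05, while 0 passed when adjusted over the list alone (lowest limma adjusted p = 0.0626). Camera called the list higher (adjusted p = 2.26e-13), but not with an estimated correlation of 0.526 among its genes (adjusted p = 0.155 with an estimated correlation). The permutation test of the list mean gave p = 0.0188 (adjusted p = 0.254), and 9 of the 10 hypersensitive arrays lay above the tolerant median. HERC5, a ligase for the ubiquitin-like protein ISG15, had a log2 difference of 0.41 (SE 0.13), OAS3, an antiviral oligoadenylate synthetase, 0.37 (SE 0.14), and IFI44 0.67 (SE 0.28). Without 1 hypersensitive library the difference of the list mean was 0.18. It was 0.14 among the numbered arrays (8 hypersensitive, 6 tolerant) and 0.78 among the lettered ones (2 and 4). That same library was 1 of the 2 lettered hypersensitive arrays, with a list level of 1.08 against 0.10 in the other. The 0.78 thus rests largely on it.

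The heat shock list holds chaperones and co-chaperones that are induced by protein damage. All 12 tested members were lower in hypersensitive patients and 5 had an unadjusted p under 0.05, with 0 past the threshold adjusted over the list alone (lowest limma adjusted p = 0.0989). Camera called the list lower (adjusted p = 6.2e-09), which was lost when its correlation was estimated (adjusted p = 0.152 with an estimated correlation). The permutation p of the list mean was 0.00917 (adjusted p = 0.248), and 0 of the 10 hypersensitive arrays lay above the tolerant median. DNAJB1, a co-chaperone of HSP70, had a log2 difference of -0.34 (SE 0.14), HSPD1, the mitochondrial chaperonin, -0.24 (SE 0.090), and HSPA1A, an inducible HSP70 that shares probes with a near-identical copy, -0.32 (SE 0.14). The difference of the list mean was -0.15 among the numbered and -0.18 among the lettered arrays.

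**Figure D2:**
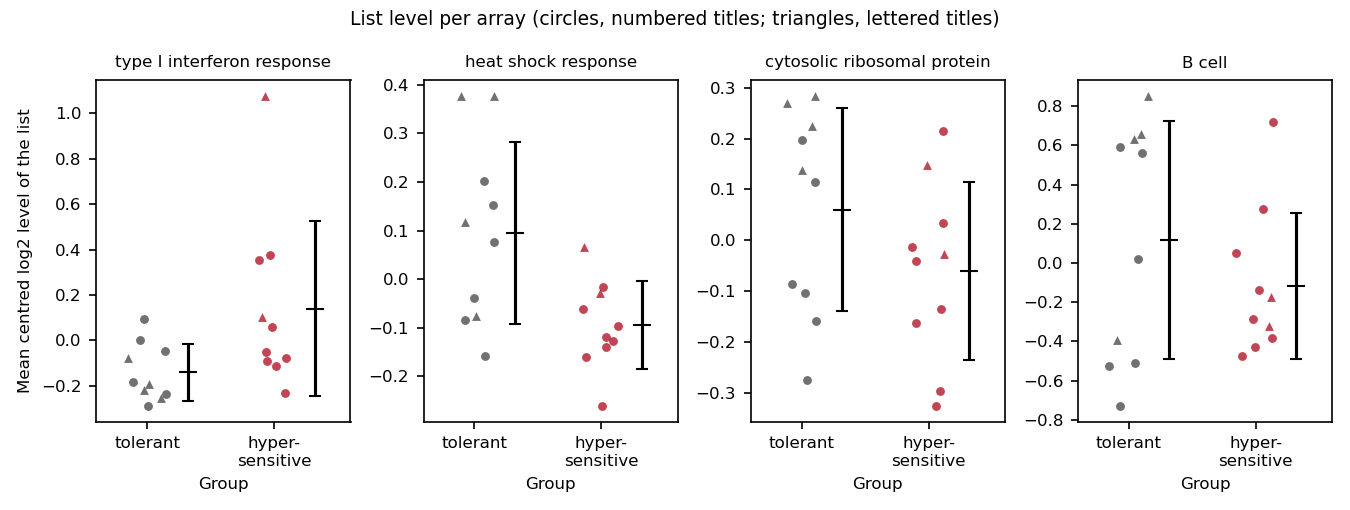
Mean centred log2 level of 4 gene lists (y axes, scaled separately) in each of 10 tolerant (grey) and 10 hypersensitive (red) arrays (x axes), with circles for numbered and triangles for lettered titles; horizontal offsets only separate the points. Black marks show group means and SDs; all but 1 of the hypersensitive arrays lie above the tolerant median for the interferon list, and none does for the heat shock list.

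Another 5 lists were called lower by camera with the preset correlation, each lost with an estimated correlation. Cytosolic ribosomal protein genes were lower in 11 of 11 tested members, with a mean log2 difference of -0.12 (adjusted p = 1.23e-04, and adjusted p = 0.767 with an estimated correlation); RPL10A had -0.26 and RPS3 -0.12. Markers of B cells, a cell type the selection should remove, were lower in 10 of 11 members, with a mean of -0.23 (adjusted p = 0.0118, and adjusted p = 0.767 with an estimated correlation). CD79A, a part of the B cell receptor, had -0.44 (SE 0.22). The B cell difference was 0.016 among the numbered and -0.69 among the lettered arrays. Proliferation genes were lower in 8 of 9 members, with a mean of -0.11 (adjusted p = 0.0306, and adjusted p = 0.767 with an estimated correlation). AURKB, a mitotic kinase, had -0.23 and PCNA, a replication clamp, -0.22; without 1 tolerant library these were -0.14 and -0.13. Immediate early genes were lower in 14 of 18 members, with a mean of -0.16 (adjusted p = 0.0470, and adjusted p = 0.767 with an estimated correlation), led by KLF6 at -0.52 (SE 0.20) and JUN at -0.68 (SE 0.33). T cell identity genes were lower in 10 of 13 members, with a mean of -0.12 (adjusted p = 0.0470, and adjusted p = 0.767 with an estimated correlation); CD3D had -0.32 and CD3G -0.26. None of the 27 list means passed the permutation test after adjustment, and fry called 0 of 26 lists (2 with an unadjusted p under 0.05, and 2 by camera with an estimated correlation).

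Leaving out 1 array at a time ended the camera call of the proliferation list in 7 of 20 fits (adjusted p = 0.670 without 1 tolerant library, with a list mean difference of -0.024), of the B cell list in 6 (list mean difference -0.15 without 1 tolerant library), of the immediate early list in 11 and of the T cell identity list in 12. The difference of the T cell identity list was -0.062 without 1 hypersensitive library, and that of the immediate early list -0.075 without 1 tolerant library; CD3G had -0.17 without 1 tolerant library. In the brightest genes too few proliferation genes were left for camera, and their mean difference turned to 0.064. Among the numbered and the lettered arrays, the differences were -0.038 and -0.17 for ribosomal protein genes, -0.20 and 0.089 for proliferation genes, -0.043 and -0.52 for immediate early genes, and -0.15 and 0.060 for T cell identity genes. With title style as a block, camera no longer called the T cell identity list (adjusted p = 0.0826), with a mean difference of -0.090 against -0.12 before, and the ribosomal difference was -0.075 against -0.12.

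Functional groups of CD8 T cells did not pass in the fit as designed. The 6 CD8 T cell markers were all lower, with a mean log2 difference of -0.076 (camera adjusted p = 0.504); CD8A had -0.087, CD8B -0.099 and GZMK -0.14. The mean was -0.18 among the numbered and 0.16 among the lettered arrays, and without 1 tolerant library it was -0.0040, with CD8A at -0.028 and CD8B at 0.012; GZMK had -0.0033 without another tolerant library. Of 18 cytotoxic effector genes, 12 were lower and 6 higher, with a mean of -0.062 (adjusted p = 0.403). That mean joined opposite directions, -0.30 among the numbered and 0.49 among the lettered arrays, and ran from -0.13 to 0.0026 with 1 array left out. Camera called the list lower in 2 of these 20 fits (lowest adjusted p = 0.0122) and with marker levels as covariates (mean difference -0.17, adjusted p = 5.93e-04). These calls used the preset correlation. The correlation was estimated only in the fit as designed, where camera gave the effector list adjusted p = 0.767. GNLY, which encodes granulysin, had a log2 difference of 0.13 (95% interval -0.30 to 0.55), GZMB -0.015 (-0.39 to 0.36) and PRF1 0.034 (-0.38 to 0.45). KLRG1, a receptor of differentiated effector cells, had -0.34 and CCL5 -0.19. With 1 array left out, GNLY had values down to 0.015 and CCL5 up to -0.11, while GZMB turned to 0.048 and PRF1 to -0.069. Naive and memory T cell genes were higher in 4 and lower in 8 members, with a mean of -0.013 (adjusted p = 0.979); CD27 had -0.19 and NELL2 0.20. This mean joined 0.23 among the numbered with -0.18 among the lettered arrays, and ran from -0.11 to 0.095 with 1 array left out. CD27 had -0.050 without 1 hypersensitive library and NELL2 0.032 without 1 tolerant library. Genes of T cell activation and inhibitory receptors were higher in 6 of 9 members (median 0.038, mean -0.0064, adjusted p = 0.657), with CD69, an early activation marker, at -0.52 and HAVCR2 at 0.31. T cell receptor signalling genes were lower in 12 of 16 members, with a mean of -0.040 (adjusted p = 0.403); MALT1 had -0.14 and RASGRP1 -0.15. Among the numbered and the lettered arrays, the receptor list had -0.078 and 0.25 and the signalling list -0.080 and 0.090. With 1 array left out, the receptor mean ran from -0.036 to 0.029 and the signalling mean from -0.056 to -0.014; HAVCR2 had values down to 0.19, and MALT1 and RASGRP1 up to -0.083 and -0.079. Class I antigen processing genes were also lower in 12 of 16 members, with a mean of -0.071 (adjusted p = 0.0508). HSPA5 had -0.28 and CANX -0.20, both chaperones of the endoplasmic reticulum. Of 6 tested cytokine and chemokine genes 5 were lower, with a mean of -0.12 (adjusted p = 0.158), and TNF had -0.31 (SE 0.13). The cytokine and chemokine mean ran from -0.24 to -0.016 with 1 array left out, and camera called that list lower in 3 of these 20 fits. The antigen processing mean was -0.14 among the numbered and 0.11 among the lettered arrays, and that list was called lower in 7 of 20 fits with 1 array left out (mean difference -0.089 to -0.042). With title style as a block, camera called the antigen processing list (mean difference -0.066, adjusted p = 0.0244) and the cytokine and chemokine list (-0.17, adjusted p = 0.0398) lower. These calls used the preset correlation. Only the fit as designed was run with an estimated correlation, and camera there gave adjusted p = 0.767 for each of these lists. Cell death genes were higher in 9 and lower in 6, with a mean of 0.0048 (adjusted p = 0.619); PMAIP1 had -0.40 and TNFSF10, the death ligand TRAIL, 0.23. This mean ran from -0.0059 to 0.020 with 1 array left out, and PMAIP1 had values up to -0.24. IFNG lay below the limit for testing and had a log2 difference of -0.37 (95% interval -0.82 to 0.085).

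Genes that activate or detoxify sulfonamides were of interest because the drug reaction has been linked to reactive metabolites. Of 13 tested members, 6 were higher and 7 lower, with a median log2 difference of -0.0056 and a mean of -0.069 (camera adjusted p = 0.632). The mean was -0.13 among the numbered and 0.019 among the lettered arrays, and ran from -0.11 to -0.036 with 1 array left out. MPO, a neutrophil peroxidase that can oxidise sulfonamides, had -0.71 (SE 0.30), with an SD of 0.29 in hypersensitive and 0.99 in tolerant patients. It is also a member of the granulocyte list. CYB5A and CYB5R3, which together reduce the hydroxylamine metabolite, had log2 differences of -0.28 (SE 0.20) and 0.054 (SE 0.050), and -0.17 and 0.026 without 1 hypersensitive library. SLC23A2, a vitamin C transporter, had 0.17 (SE 0.085). MTARC1, NAT1, GCLC and GCLM lay below the limit for testing, with log2 differences of 0.024, 0.026, 0.025 and 0.056. Oxidative stress genes were higher in 5 and lower in 8 members, with a mean of -0.043 (adjusted p = 0.619), or -0.038 among the numbered and 0.032 among the lettered arrays. PRDX1 had -0.13 and SOD1 -0.24. Hypoxia and glycolysis genes were higher in 9 and lower in 10, with a mean of -0.025 (adjusted p = 0.657); GAPDH had -0.24 and PFKFB4 0.15. The oxidative stress mean ran from -0.076 to -0.012 with 1 array left out, and the hypoxia and glycolysis mean from -0.064 to -0.00071, where SOD1 had values up to -0.12 and PRDX1 up to -0.085.

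Over single genes, limma called 0 of 11189 (lowest adjusted p = 0.9997). At an unadjusted p under 0.05 there were 187 genes, 59 higher and 128 lower in hypersensitive patients, where chance gives 559 on average. The exact Wilcoxon rank-sum test also called 0 genes, with 177 at an unadjusted p under 0.05. The 12 higher genes named by the rule included AOAH, an enzyme that inactivates endotoxin, at 0.44 (SE 0.18), and AOAH-IT1, an intronic transcript of the same gene that is uncertain for that reason, at 0.53 (SE 0.20). They also included CD300E, a monocyte receptor, at 0.46 (SE 0.18), GPCPD1 at 0.33, DDX60L at 0.33, OAS1 at 0.36, EPSTI1 at 0.40, USP18 at 0.36 and its near copy USP41P at 0.35. USP18 and USP41P are uncertain, since their probes can read both genes. Without 1 hypersensitive library, USP18 had 0.20, USP41P 0.23 and IFI44 0.43, and without another GPCPD1 had 0.20, CD300E 0.33 and AOAH-IT1 0.39. The latter library had the highest monocyte list level of all arrays, 1.81. Among the lower genes were UGCG, which makes glucosylceramide, at -0.44 (SE 0.14), the histone gene H2BC12 at -0.51 (SE 0.19) and SCD, a fatty acid desaturase, at -0.36 (SE 0.14). H2BC12 is uncertain, since histone genes can share probes. DNAJC15 had -0.35, SCARNA17 -0.32, MRPL54 -0.31 and HDGFL3 -0.38.

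**Figure D3:**
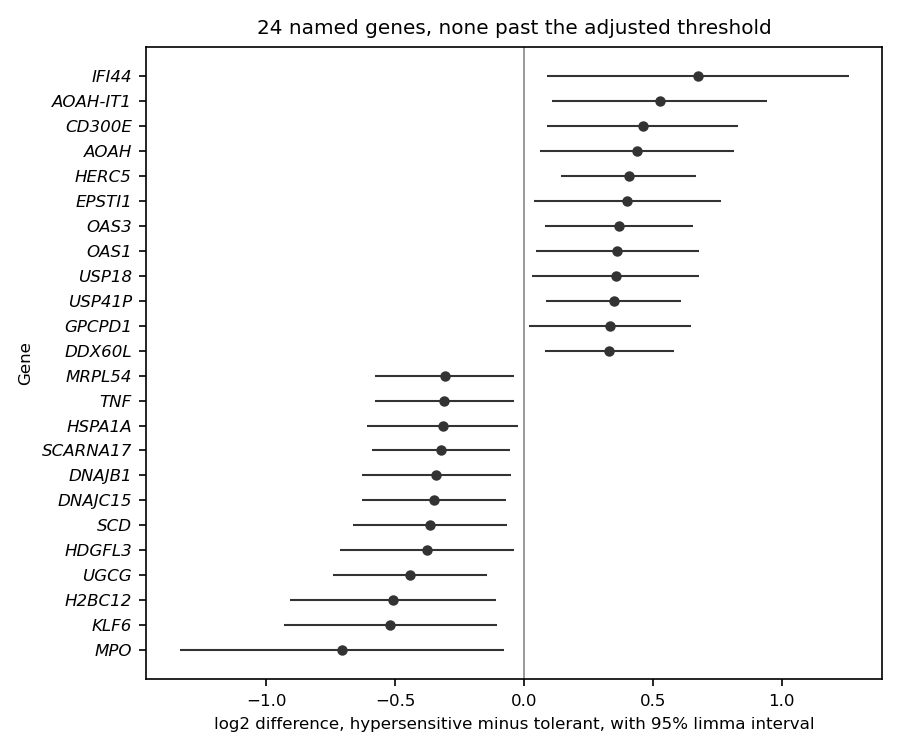
log2 difference between 10 hypersensitive and 10 tolerant patients (x axis) for the 24 genes named by the rule for genes short of the threshold (y axis), with 95% limma intervals. The genes were chosen for a small unadjusted p, so the intervals exclude 0 by selection; all have a limma adjusted p of 0.9997.

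The median distance from a gene's log2 difference to either end of its 95% interval was 0.16. For 11114 of the tested genes, or 99.3%, the interval excluded a difference of 2-fold either way. These intervals were set gene by gene, without adjustment over genes. Signal above background could not be judged, so a narrow interval can also come from a gene near background. Genes below the limit for testing are not covered, among them IFI44L, whose group means lay more than 2-fold apart.

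The second comparison asked whether the samples of the groups held different cells, since the selection depletes other cell types without removing all of them. Marker levels of the other cell types did not differ past the threshold in the permutation test of any list. The monocyte list differed by -0.0017 (95% interval -0.66 to 0.65; adjusted p = 0.996), the NK cell list by 0.065 (-0.28 to 0.41; adjusted p = 0.898) and the platelet list by -0.090 (-0.60 to 0.43; adjusted p = 0.918). By camera, the NK cell list was higher in 8 of 12 genes (adjusted p = 0.403) and the platelet list lower in 9 of 13 (adjusted p = 0.760). Without 1 hypersensitive library the platelet difference was -0.28, and camera called that list lower (adjusted p = 2.57e-05). Without another it was -0.017, and among the numbered and the lettered arrays it was -0.028 and -0.36. An estimated correlation was used only in the fit as designed, where camera gave the platelet list adjusted p = 0.945. The NK cell difference ran from -0.0065 to 0.13 and the monocyte difference from -0.20 to 0.11 with 1 array left out, and camera called the monocyte list higher in 1 of these 20 fits (adjusted p = 0.0232). In the fit as designed, the only fit with an estimated correlation, camera gave the monocyte list adjusted p = 0.767. Among the numbered and the lettered arrays, the NK cell difference was 0.035 and 0.25, and the monocyte difference -0.045 and -0.10. FCER1G, a signalling chain of NK and myeloid cells, had a log2 difference of 0.33, NCR3 -0.19, GP9 0.092 and GNG11 -0.26. Monocyte genes went both ways, with CLEC7A at 0.56 and LYZ at -0.61 (8 of 14 higher, median 0.11, camera adjusted p = 0.403). With 1 array left out, CLEC7A had values down to 0.32, GP9 ran from 0.062 to 0.14 and GNG11 from -0.59 to -0.13.

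CD4 T cell markers were higher in 3 of 5 genes (median 0.011, mean -0.014, camera adjusted p = 0.668); CD4 had 0.086 and CCR4 -0.093. Their list mean ran from -0.056 to 0.029 with 1 array left out, where CD4 had values down to 0.035 and CCR4 turned to 0.061. Granulocyte genes had the lowest list mean, -0.24 (95% interval -0.72 to 0.24), with 8 of 14 lower (camera adjusted p = 0.150) and LTF at -0.84 (SE 0.41). Camera called the granulocyte list lower in 10 alternative fits, 4 of them with 1 array left out, among them title style as a block (mean difference -0.28, adjusted p = 0.0116) and the brightest genes (-0.41, adjusted p = 0.0298). These calls used the preset correlation. The correlation was not estimated in these fits, but only in the fit as designed, where camera gave this list adjusted p = 0.767. Its difference was -0.39 among the numbered and -0.013 among the lettered arrays, and -0.32 to -0.14 with 1 array left out. Plasma cell genes were lower in 6 of 8, with a mean of -0.11 (adjusted p = 0.548); IGHM had -0.33 and DERL3 -0.052. Their mean was -0.19 among the numbered and 0.26 among the lettered arrays; without 1 hypersensitive library it was -0.037, with IGHM at -0.20, and without another DERL3 had -0.016. Dendritic cell genes were lower in 3 of 5, with a mean of -0.047 (adjusted p = 0.657); TCF4 had -0.13 and CD1C -0.22. Here the mean was 0.075 among the numbered and -0.18 among the lettered arrays, and -0.098 to -0.0086 with 1 array left out, where TCF4 had values up to -0.075 and CD1C up to -0.10. Red cell genes were higher in 5 of 5, with a mean of 0.17 (adjusted p = 0.200); SLC4A1 had 0.31 and SELENBP1 0.069. Without 1 hypersensitive library the red cell difference was -0.077, with SLC4A1 at 0.015 and SELENBP1 at -0.017, and without 1 tolerant library camera called the list higher (0.32, adjusted p = 0.00981). With an estimated correlation, used only in the fit as designed, camera gave the red cell list adjusted p = 0.767. The list for gamma delta and MAIT T cells had 4 tested genes and was not tested by camera; its mean difference was -0.14 (permutation adjusted p = 0.898; -0.23 to -0.080 with 1 array left out), and KLRB1, a receptor of MAIT cells, had -0.42 (SE 0.26).

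The third comparison concerned the spread among patients, because the series describes a range of cytotoxicity phenotypes that no label gives per sample. Hypersensitive patients varied more for 63.9% of the tested genes. The median SD was 0.178 in hypersensitive and 0.159 in tolerant patients, a median variance ratio of 1.33 (log2 0.41). The share of 100 splits with a ratio as far from 1 in either direction was 0.33, so the difference was within what other splits gave. Without the 3 arrays farthest from the median array, all of them hypersensitive, the log2 ratio was -0.51, and without 1 hypersensitive library it was 0.18.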

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

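Of the tests here, the count of genes past the threshold over splits, the counts of splits for single lists, the correlation between list levels, the fit with a slope for each group and the fit with 2 principal components were chosen after the result was seen. Within each group of 10 arrays, 54 list levels and 160 gene levels were searched for an array that stood far from the rest, by the gap to its nearest neighbour as a share of the group's range (critical value 0.466). This was met 27 times among 214 groups, where chance gives about 1 in 20, or 10.7. Many of these genes belong to the same lists or the same arrays, so the 27 are not independent.

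Interferon genes stood out in 1 hypersensitive library. Its gap was 0.537 of the range for the type I interferon list, and for single genes in the same library 0.552 (HERC5), 0.7 (USP41P), 0.498 (IFI44) and 0.695 (USP18); EPSTI1 had a gap of 0.562 in 1 tolerant library. Another hypersensitive library stood high for the hypoxia and glycolysis list (0.586) and the platelet list (0.592), and for AOAH-IT1 (0.598), GPCPD1 (0.671), HDGFL3 (0.535), CLEC7A (0.47) and GNG11 (0.579); it stood low for AURKB (0.546) and DERL3 (0.582). A different hypersensitive library stood high for the red cell list (0.563), SLC4A1 (0.695) and SELENBP1 (0.682) and low for SCARNA17 (0.537). In 1 tolerant library proliferation genes were high, with 0.744 for the list, 0.586 for AURKB and 0.693 for PCNA. The tolerant library with high EPSTI1 was also high for RASGRP1 (0.66) and GCLM (0.677). Of the remaining cases, TNF (0.48) and GP9 (0.535) were low in the same hypersensitive library, and GCLM (0.474) was high in another.

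The higher interferon list was weighed against technical explanations. A single library as the whole cause is argued against, since the smallest difference with 1 array left out was 0.176 of 0.28, still over the bound set for that test. A shared shift of the deposited gene values is argued against, since the array medians over the 22378 genes differed by only 0.00046 between the group means. The interferon difference was 0.280 (SE 0.125) with the array median as a covariate, 0.289 with arrays shifted to 1 median and 0.291 after quantile normalization again. The medians had been made nearly equal before, so these fits could change little. Array brightness before normalization stays open, since scanner intensities were not used here. Other cell types stay open as well: with monocyte, B cell, NK cell and platelet marker means as covariates the difference was 0.200 (SE 0.128), too imprecise to decide. Recent infection or another source of interferon unrelated to the drug reaction was not tested, and the group difference itself stays open as a biological explanation, with 3 of the 100 splits, the real one included, giving an interferon camera p as small.

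For the lower heat shock list, a single library is argued against by a smallest difference of -0.158 with 1 array left out. With 4 marker means as covariates the difference was -0.178 (SE 0.0738), past the bound set. Of these lists, the monocyte, NK cell and platelet means differed little between the groups (-0.0017, 0.065 and -0.090), so they could hardly move it. The fit argues at most against B cells, whose list mean differed by -0.23. Granulocytes (-0.24) and further cell types were not in that fit, so other cell types stay open. Handling stress shared with immediate early genes stays open: the difference was -0.181 (SE 0.0684) with that list as a covariate, but the levels of both lists ran opposite ways (r = -0.658 among hypersensitive and 0.555 among tolerant patients), and with a slope for each group it was -0.15 (SE 0.059) at the hypersensitive and -0.21 (SE 0.059) at the tolerant mean, the former short of the bound set. RNA yield or quality shared with the ribosomal protein genes stays open, since the difference was -0.143 (SE 0.0624) with that list as a covariate. Over the 20 arrays the heat shock and ribosomal levels were correlated (Pearson's r = 0.566, permutation p = 0.00908, adjusted p = 0.0363 over 4 relations, of which no other passed). Spearman's rho was 0.633 (permutation p = 0.00353). Pearson's r was 0.439 without the 2 farthest arrays, 0.259 among the 14 numbered and 0.70 among the 6 lettered arrays. Within the groups it was 0.830 among hypersensitive and 0.377 among tolerant patients. Both lists were lower in hypersensitive patients, so the correlation over all arrays includes the group difference. A biological difference between the groups stays open, and 1 of the 100 splits, the real one, gave a heat shock camera p as small. Like the count for interferon genes, this covers 1 list picked for its small p among 26, so it is not adjusted for that choice. Over all lists, 9 of the 100 splits, the real one included, had some list at the still smaller interferon camera p.

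Chance could not be excluded for the number of lists called or of genes under 0.05. Of the 100 splits of the 20 arrays, 57 called at least as many lists by camera as the real 7, and the highest other count was 16; 9 had some list at a p as small as that of the interferon list. For genes past the threshold the splits decide nothing, because all 100 must give at least the 0 of the real split (highest other count 1). The 187 genes under 0.05 were matched or undercut in 24 of the 100 splits, whose others ranged from 55 to 2245, so the arrays share a structure that single splits can follow. Variation on the first 2 components as the reason for the low count stays open: 290 genes lay under 0.05 with both as covariates, short of the 559 chance gives, but 25 of the 100 splits gave as few in that fit (104 to 2112 over the others).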

How the results depend on the processing

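The fits without the 3 farthest arrays and with 2 principal components were chosen after seeing the data. The count of genes past the threshold was 0 in every alternative run (lowest adjusted p = 0.200), including the threshold of 0.1, and no gene of the 24 in the plot of named genes changed sign, while 13 of all 75 named genes did in 39 of 2223 values. Genes with an unadjusted p under 0.05 numbered 662 with array weights, 492 with marker levels as covariates, 485 with no filter, 475 over all transcript clusters, 290 with 2 components, 241 without the 3 farthest arrays, 85 in the brightest genes and 114 to 475 with 1 array left out. The 7 lists called by camera became 0 with an estimated correlation, 0 with fry and 4 in the brightest genes, where fewer genes were tested, and ranged from 3 to 10 with 1 array left out. With an estimated correlation the interferon list had adjusted p = 0.155, the heat shock list 0.152 and each of the other 5 lists 0.767; fry gave 0.579, 0.256 and 0.895. That these calls rest on treating a list's genes as nearly independent follows from the construction of these tests. The interferon and heat shock lists passed in all other camera fits. In the brightest genes the T cell identity list had adjusted p = 0.0816, the immediate early list 0.0948 and the B cell list 0.0665, though their mean differences did not shrink (-0.13, -0.21 and -0.27, against -0.12, -0.16 and -0.23 before). The T cell identity list had 0.102 after quantile normalization again, 0.0826 with title style as a block, 0.664 with array weights, 0.236 with 2 components and 0.933 without the 3 farthest arrays. In the last 3 of these fits its difference shrank from -0.12 to -0.048, -0.045 and -0.011. The proliferation list had 0.150 with array weights and 0.0510 without those 3 arrays, which also took the ribosomal list to 0.209 (difference -0.034, and -0.049 with 2 components, against -0.12). The immediate early list had 0.502 with marker levels as covariates, where its difference shrank from -0.16 to -0.095, and 0.0750 on ranks. Its difference grew to -0.35 without those 3 arrays (adjusted p = 9.80e-11) and -0.27 with 2 components (adjusted p = 3.59e-06). With 1 array left out, adjusted p ran from 0.00883 to 0.308 for T cell identity, 0.00553 to 0.670 for proliferation, 3.32e-05 to 0.471 for immediate early and 2.63e-05 to 0.141 for B cell genes. The naive and memory list, not called in the fit as designed, was called higher without the 3 farthest arrays (adjusted p = 0.00103) and with 2 components (0.0338), against a lower direction before. These calls used the preset correlation. In the fit as designed, where its direction was lower, camera with an estimated correlation gave that list adjusted p = 0.992. The fits that called it were not run with an estimated correlation. Among lists not called, 20 of 238 fits on all arrays or without the 3 farthest made a call, over 7 lists. Genes short of the stricter filter have no value there, and lists left with under 5 genes only a mean: the proliferation list mean turned to 0.064 and the dendritic cell list mean to 0.076. List means passed the permutation test in 1 alternative, without the 3 farthest arrays, where 1 list passed: the interferon list, at 0.40 (adjusted p = 0.0478; 0.0478 to 0.816 over its alternatives). The log2 variance ratio turned to -0.51 without those arrays (share of splits 0.04), which follows from removing the most deviant arrays of 1 group; it was 0.18 to 0.53 with 1 array left out. The 3 farthest arrays lay below their group's interferon mean of 0.14 (-0.11, -0.23 and -0.079), so leaving them out raised that difference by construction. The same holds for their naive and memory levels (-0.98, -0.56 and -0.35, group mean -0.0065). Their immediate early levels (0.50, 0.64 and -0.064) lay above the group mean of -0.081, so that difference fell further below 0 without them. The causes of the other changes were not tested. Signal over background was not available here, so what dim genes hide stays unknown.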

Other observations

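The granulocyte genes and IFI44L named here, and their tests, were chosen after their values were seen; the test of the main axis was set before. Several genes of neutrophil granule proteins, picked for their low values, had lower group means in hypersensitive patients. The fixed granulocyte list, with 8 of 14 genes lower, was not called in the fit as designed. Camera gave it adjusted p = 0.150, and 0.767 with an estimated correlation. The lowest tested difference was that of DEFA4, a defensin of neutrophil granules, at -0.97, followed by OLFM4 at -0.96, and CAMP had -0.90, CEACAM8 -0.93, LTF -0.84 and MPO -0.71; none passed (limma adjusted p = 0.9997 each). CSF3R had 0.096, CXCR1 0.26, CXCR2 0.22 and FCGR3B 0.16. Over 7 granule genes of the granulocyte list (MPO, LTF, LCN2, MMP9, CAMP, ELANE and CEACAM8, without DEFA4 and OLFM4) the mean log2 difference was -0.61. The SD was 0.51 in hypersensitive and 0.99 in tolerant patients (permutation p = 0.10). Over those 4 receptor genes the difference was 0.18 (permutation p = 0.540). The parts were chosen on the same values, so these p-values cannot serve as support. The granule difference was -0.88 among the numbered and -0.18 among the lettered arrays, and -0.77 to -0.47 with 1 array left out; for the receptor genes these were 0.030, 0.30 and 0.016 to 0.31. IFI44L, an interferon-induced gene below the limit for testing, had a mean of 5.38 ± 1.58 in hypersensitive and 4.18 ± 0.43 in tolerant patients (SD, n = 10 each).

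The main axis of variation among the 20 arrays held 26.6% of the variance and its difference between the groups did not pass (permutation p = 0.345). A hypothesis was that it may follow the balance of naive and effector T cells. Computed without the genes of those lists, its correlation was 0.696 with the naive and memory list (Spearman's rho = 0.669, permutation p = 0.00078 and 0.00161, adjusted p = 0.00702 and 0.0145) but 0.0939 with the cytotoxic effector list (rho = 0.0526, permutation p = 0.691 and 0.824, adjusted p = 0.778 and 0.894), which argues against such a balance. Among the 14 numbered and the 6 lettered arrays, r was 0.586 and 0.457 with the naive and memory list, and 0.288 and -0.345 with the effector list. The axis followed the ribosomal protein list most closely (r = 0.906, rho = 0.916, adjusted p = 0.00027 each over 27 relations), with r = 0.884 without the 2 farthest arrays, 0.920 among the numbered and 0.526 among the lettered arrays. It also followed T cell identity genes (r = 0.802, rho = 0.854, adjusted p = 0.00027 each; 0.851 without the 2 farthest arrays, 0.796 and 0.545 within the title styles). In all, 6 of the 27 lists passed after adjustment of Pearson's r. Only the naive and memory and the effector genes were left out of the axis. Other genes, those of the ribosomal and T cell identity lists included, helped to form it, so part of their relations is built in. These relations were found in the same family of tests, and RNA yield and the share of T cells were not measured apart from the arrays.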
